A study of Mus musculus with 8 samples.

How the data were processed

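The samples were 8 arrays of dendritic cells sorted from inguinal lymph nodes, 4 from mice fed CD and 4 from mice fed HFD, all treated with imiquimod. Per the labels' protocols, the mice received 62.5 mg of cream with 5% imiquimod on abdominal skin each day over 5 days and were killed 24 h after the last dose, while the series design gives 6 days. RNA was isolated with a Picopure kit, and 5 ng per sample was amplified and labelled with a whole-transcriptome kit, per the labels' protocols. The deposited values are log2 levels per probe set made with RMA and affy, per the submitters' processing notes, with no versions. RMA corrects the background, sets the arrays to a common distribution and summarises the probes of a set. The chip definition and the genome build are not given in the sources used here, so no coordinates are printed. Values lay between 1.11 and 13.6, the range of log2 RMA values.

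Groups and replicate numbers were taken from the sample titles. The descriptions of the HFD arrays conflict with their titles, source names and protocols, and the titles were used. Nothing in the labels ties equal replicate numbers of the diets together, so the numbers were not taken as pairs in the comparison. The replicates are labelled biological, and no label says how many mice gave cells to each.

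Probe sets were named through GEO's platform annotation, which can be old. Of 41345 probe sets, 23521 had 1 gene, 1820 had several and were not named, and 16004 were not listed and are unnamed here. Symbols of 23328 probe sets were updated by Entrez identifier through the GRCm38.p6 gene table, used for names only, and 193 kept the platform's symbol. Of the genes, 1082 had several probe sets, and the brightest over all 8 arrays was used, which left 22180 genes. No filter on level was applied.

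The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, HFD minus CD, all 8 arrays, no covariate), with Benjamini-Hochberg adjustment over 22180 genes and a threshold of 0.05. Fixed gene lists were tested with limma's camera at its preset correlation of 0.01, adjusted over 43 lists, for lists with at least 5 measured members. Of 1059 list entries 950 were measured, the others having no probe set with 1 gene. Whole profiles were compared by the mean distance (1 minus Pearson's r) between diets minus that within diets over the 2000 most variable genes, with an exact permutation test over the 35 splits of 8 arrays into 4 and 4. Differences of list means were tested by the exact permutation test over the same splits, two-sided, and relations across arrays by all 576 rearrangements within the diets, one-sided. The smallest p that the splits allow is 0.0286.

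Named genes followed a rule. In each direction they were the 12 with the smallest p among those that passed. Where under 5 passed, they were the 8 with the smallest p and an absolute log2 difference of at least 0.58. To these were added every gene of the candidate list, and the 4 members with the smallest p of each called list. Predicted genes, RIKEN clones, microRNA, Snor and receptor families of smell were counted and not named. Other list members named passed when adjusted over their list alone, or are named as examples chosen after their values were seen. The tests, lists, naming rule and most alternatives were fixed before the data were examined.

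The alternatives were an intensity trend with a robust prior, array weights, a filter at the median level, quantile normalization, centring on the array median, the average of a gene's probe sets, the replicate number as a block, the first residual component as a covariate, each array left out in turn, a threshold of 0.1, camera with an estimated correlation, fry, and all genes for the profile distance. Chosen after seeing the data were a test of every probe set on its own and the XBP1 and ATF6 list without genes of the plasma cell list.

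The fit was tested on simulated data for HFD against CD with 22180 genes and independent noise. Of genes seeded with a log2 change of 0.5, 1 and 1.5, it recovered 20 of 50, 96 of 100 and 50 of 50, with 7 of 21980 unchanged genes called. With no change it called 0 genes and 0 lists. Genes of a list varied independently there, so the 0 lists does not show how the list test behaves with the correlated genes of real arrays.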

Results

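The data were array profiles of cells sorted as classical dendritic cells from the inguinal lymph nodes of C57/B6 male mice. Their abdominal skin had been treated with imiquimod, a Toll-like receptor 7 agonist that brings on a psoriasis-like inflammation of the skin. The mice had been fed either a diet labelled CD or a high-fat diet (HFD, labelled 60%), and each diet had 4 arrays, numbered as biological replicates 1 to 4. Cells were sorted as CD3, CD19, CD64 and Ly6G negative and CD11c and MHC class II positive, and 5 ng of RNA per sample was amplified and labelled. Every mouse received imiquimod, so the only comparison was HFD against CD under treatment, and the question it addressed was how the diet altered the expression profile of dendritic cells draining the inflamed skin. The titles and source names placed all 4 HFD arrays in that group. The free-text descriptions differed from the titles for these arrays: that of HFD replicate 1 named the diet CD, and those of HFD replicates 2 to 4 named GM-DC given a mock treatment with PA for 24 h. Median log2 levels over 41345 probe sets lay between 4.88 and 4.94 on the 8 arrays, and Pearson's r over these probe sets lay between 0.980 and 0.986 for every pair of arrays. Levels are deposited log2 values and their number, 4 per diet, limits the precision.

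The 6 genes that rose past the threshold over all 22180 genes in HFD were 3 immunoglobulin light-chain segments, Tmed6, Creb3l2 and Edem1. Igkv4-59 was 2.27-fold higher, from 8.42 ± 0.27 in CD to 9.60 ± 0.14 in HFD (log2, mean ± SD, n = 4 each; limma adjusted p = 0.0274). Igkv9-120 was 1.93-fold higher and Igkv15-103 was 1.69-fold higher, both with a limma adjusted p of 0.0274. Tmed6, a member of the p24 family of vesicle cargo receptors, had the largest rise of the genes that passed, 2.70-fold (log2 difference 1.43 ± 0.19 SE, limma adjusted p = 0.0416). Creb3l2, a transcription factor that is released from the endoplasmic reticulum (ER) membrane, rose 1.77-fold (log2 0.83 ± 0.10 SE, limma adjusted p = 0.0400), and Edem1, which routes misfolded glycoproteins to degradation, rose 1.69-fold (limma adjusted p = 0.0416). The only gene that fell was Rnu3a, a small nucleolar RNA gene, by 0.67 on the log2 scale (limma adjusted p = 0.0416). Immunoglobulin segments have near-identical relatives, and a probe set of one segment can bind transcripts of others.

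In all, 6 genes rose and 1 fell, and all 4 HFD arrays lay on the same side of all 4 CD arrays for each of these 7. At an unadjusted p under 0.05 there were 1075 genes higher and 1079 lower, 2154 together, where 1109 would be met by chance. The calls depended on single arrays: with limma, no gene passed without CD replicate 2, CD replicate 4, HFD replicate 2, HFD replicate 3 or HFD replicate 4, and 1 passed without CD replicate 1. Without HFD replicate 1, whose description named the other diet, 22 genes rose and 15 fell, all 7 among them, and without CD replicate 3 there were 7 and 2, with 5 of the 7 kept. With a variance prior that followed the level, limma called 107 genes higher and 11 lower, all 7 genes among them, and with every probe set of the table tested on its own it called 0. With the replicate number as a block it called 3 higher and 1 lower, and only 1 of the 7 was kept. Whole profiles over the 2000 most variable genes separated the diets, by a distance of 0.00757 (exact permutation p = 0.0286, one-sided, the smallest that the 35 splits allow), and the first component held 28.5% of their variance. The separation did not pass without HFD replicate 2 (exact p = 0.0571) or HFD replicate 3 (exact p = 0.114).

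**Figure D1:**
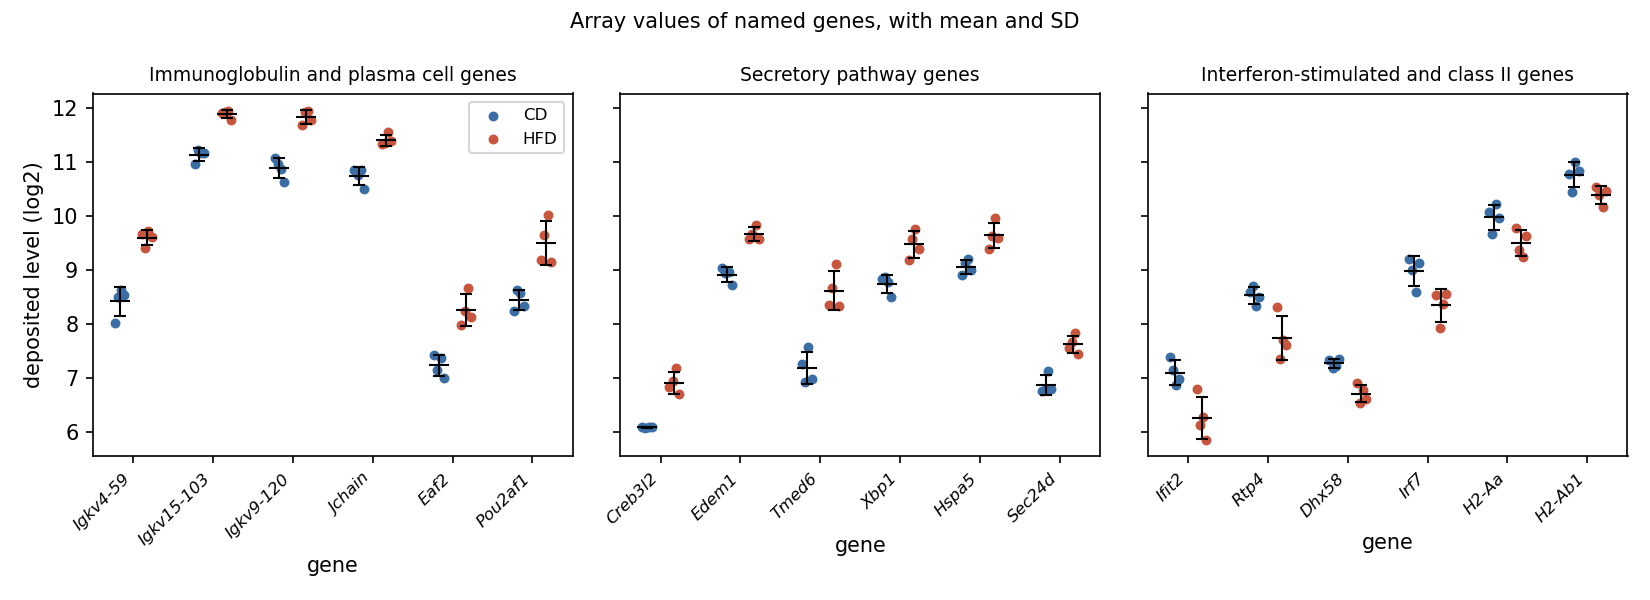
Deposited log2 level (vertical axis) of 18 genes (horizontal axis) on each of the 4 CD and 4 HFD arrays, with points for arrays and black bars for the mean ± SD. Igkv4-59 averaged 8.42 in CD and 9.60 in HFD, while Ifit2 averaged 7.09 in CD and 6.26 in HFD.

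Among lower genes too few passed for the rule, so the 8 with the smallest p and a sizeable change were read. Apart from Rnu3a, given above, these are values that did not pass over all genes. Ly6i, a Ly6 family surface antigen, differed by -1.13 (± 0.17 SE, limma adjusted p = 0.0674), and Ace, angiotensin-converting enzyme, by -0.84 (limma adjusted p = 0.126). The interferon-stimulated genes Ifit2, Ifi213 and Rtp4 differed by -0.84, -0.85 and -0.79, with limma adjusted p from 0.143 to 0.151. Nlrp1c-ps, a pseudogene of the Nlrp1 family, and Ssxb6 differed by -0.76 and -0.67, and the mean level of Ssxb6 was only 2.29 in CD.

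Of 43 gene lists fixed beforehand, limma's camera test with its preset correlation called 10 higher and 6 lower in HFD, and 9 and 9 after a quantile normalization of the deposited values. With an estimated correlation it called 0, with adjusted p from 0.118 to 0.503 over those 16 lists, and 6 of the 43 lists had an unadjusted p under 0.05. The exact permutation p of list means was 0.0286 for 4 of the 16 (the XBP1 and ATF6, heat shock, plasma cell and proliferation lists) and from 0.0571 to 0.286 for the other 12. Another split of the same 8 arrays, CD replicates 1, 3 and 4 with HFD replicate 1 against the rest, called 18 lists.

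Genes of protein folding and quality control in the ER were higher. All 32 measured targets of XBP1 and ATF6, the transcription factors of the unfolded protein response, were higher in HFD, with a median log2 difference of 0.44 (1.35-fold), and 28 of them rose when adjusted over the list alone. Over all genes 1 of them, Edem1, passed. Among the 28 were Sec24d, a COPII coat protein (0.76 ± 0.11 SE), Pdia6, a disulfide isomerase (0.70 ± 0.11 SE), Dnajb9, an Hsp70 co-chaperone of the ER lumen (0.62 ± 0.11 SE), and Derl3, a component of ER-associated degradation (1.04). The list's mean went from 8.62 ± 0.05 in CD to 9.07 ± 0.14 in HFD (SD, n = 4 each; exact permutation p = 0.0286, two-sided). Its camera call had an adjusted p = 0.118 with an estimated correlation (4.4e-37 with the preset one). The heat shock list, chaperones of the cytosol and their partners, was also higher, with 11 of 13 members above 0, a median of 0.16 and 1 member, Hsph1 (0.51), rising when adjusted over the list alone (exact permutation p = 0.0286, two-sided; adjusted p = 0.118 with an estimated correlation). Targets of ATF4 and of the kinase PERK were higher by a median of only 0.08, with 17 of 25 above 0. Of these, Asns, asparagine synthetase (0.57), and Eif2ak3, which encodes PERK (0.41), rose when adjusted over the list alone, the amino acid transporter genes Slc7a5 and Slc3a2 differed by 0.33 and 0.28 without passing, and the list had an exact permutation p = 0.0571 (two-sided) and an adjusted p = 0.355 with an estimated correlation. Without HFD replicate 3 this last list was no longer called (limma camera adjusted p = 0.0622) and its median was 0.03.

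Markers of plasma cells, which the sort was not designed to keep, moved in the same direction as the ER genes. All 10 measured members were higher, with a median log2 difference of 0.91 (1.87-fold), and 9 rose when adjusted over the list alone. They included Fkbp11 (1.22), Tnfrsf17, the receptor BCMA (1.15), Mzb1 (1.04), Eaf2 (1.02), Txndc5 (0.77) and Jchain, the joining chain of IgM and IgA (0.67), while Prdm1, the plasma cell regulator Blimp-1, differed by 0.19 without passing. The list's mean went from 8.07 ± 0.13 in CD to 8.92 ± 0.29 in HFD (SD, n = 4 each; exact permutation p = 0.0286, two-sided), with an adjusted p = 0.118 with an estimated correlation. All 18 measured immunoglobulin V and J segments, a set drawn up after the values were seen, were higher, by a median of 0.63, and 15 rose when adjusted over the set alone. After each diet's mean was removed, the mean of these segments on an array followed that of 31 XBP1 and ATF6 targets (the list without 1 gene shared with the plasma cell list) over the 8 arrays, with Pearson's r = 0.955 and Spearman's rho = 0.952, each with an exact permutation p of 0.00174 (one-sided, 0.00521 adjusted over 3 relations). Without CD replicate 3 and HFD replicate 3, the arrays farthest from the median, r was 0.903. The B cell list was higher by a median of 0.13, with 11 of 18 members above 0. Pou2af1, a coactivator of the B lineage (1.06), and the B cell receptor chain genes Cd79a (0.53) and Cd79b (0.39) rose when adjusted over the list alone, and Bank1 differed by 0.40 without passing. The list's exact permutation p was 0.114 (two-sided) and its adjusted p was 0.460 with an estimated correlation, and its call was also lost after quantile normalization (limma camera adjusted p = 0.0967) and without CD replicate 2, HFD replicate 1 or HFD replicate 2 (limma camera adjusted p from 0.0764 to 0.195).

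**Figure D2:**
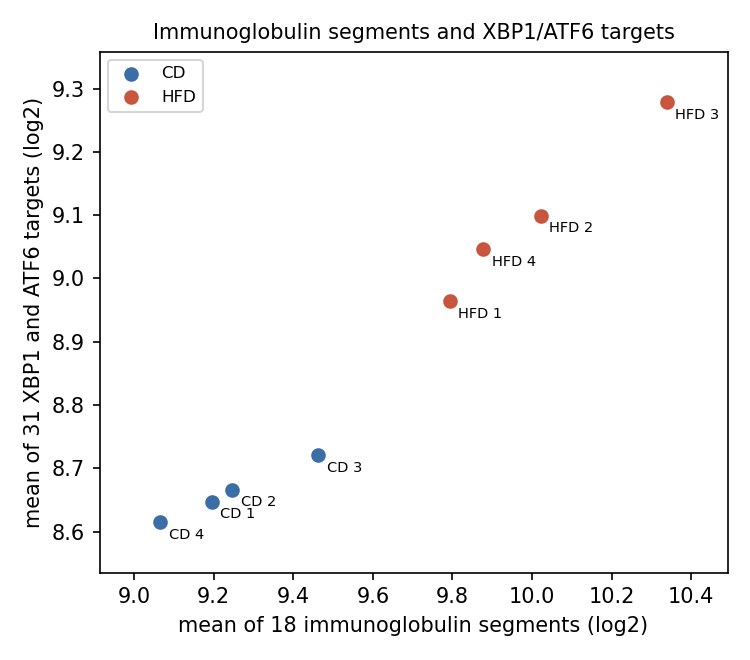
Mean log2 level of 31 XBP1 and ATF6 targets (vertical axis) against the mean of 18 immunoglobulin segments (horizontal axis), with each point an array of CD or HFD. The CD arrays lie between 9.07 and 9.46 on the horizontal axis and the HFD arrays between 9.79 and 10.3, and within each diet the arrays with higher segments have higher targets.

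Genes of the cell cycle were higher as well. Of 34 measured members of the proliferation list 33 were higher, with a median of 0.28 (1.22-fold), and 20 rose when adjusted over the list alone. Rrm2, a ribonucleotide reductase subunit, differed by 0.47 ± 0.09 (SE), the spindle factor Tpx2 by 0.49 ± 0.10, the ubiquitin-conjugating enzyme gene Ube2c by 0.52 ± 0.12, Ect2 by 0.43 ± 0.10 and Mki67 by 0.42. The list's mean went from 7.25 ± 0.11 in CD to 7.53 ± 0.05 in HFD (SD, n = 4 each; exact permutation p = 0.0286, two-sided), with an adjusted p = 0.149 with an estimated correlation.

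The 3 lists of mitochondrial metabolism had small differences that did not pass the exact permutation test of list means. Of 68 oxidative phosphorylation genes 59 were higher, by a median of 0.10, and of 24 genes of the tricarboxylic acid cycle 21 were higher, also by 0.10. Of 23 genes of fatty acid oxidation 17 were higher, by a median of 0.11. No member of these 3 lists passed when adjusted over its list alone. Values with the smallest p were those of the ATP synthase gene Atp5g3 (0.26), the complex I genes Ndufa12 (0.26), Ndufb6 (0.24) and Ndufa1 (0.25), Mdh1 (0.22), Mdh2 (0.19), Pdhb (0.18), Sdhc (0.18), Acaa2 (0.34), Ehhadh (0.35), Eci2 (0.22) and Acadvl (0.34). Exact permutation p (two-sided) was 0.0571 for oxidative phosphorylation and for the tricarboxylic acid cycle and 0.143 for fatty acid oxidation, and adjusted p was 0.370 for the first and 0.355 for each of the others with an estimated correlation.

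A list of 16 candidates, drawn up with knowledge of the study's subject (the IL-23 axis and the unfolded protein response in dendritic cells), held no gene that passed over all genes. Adjusted over the list alone, 5 rose: Xbp1 (0.74 ± 0.13 SE), the ER chaperone gene Hspa5 (0.58 ± 0.12 SE), Eif2ak3 (0.41 ± 0.10 SE), Ern1, which encodes the sensor IRE1 (0.32 ± 0.11 SE), and Tnf (0.31 ± 0.09 SE). Irf7, the regulator of type I interferon genes, fell by 0.64 (± 0.17 SE). The cytokine gene Il23a differed by -0.10 (± 0.10 SE, limma adjusted p = 0.820) and Il12b, which encodes the subunit it pairs with, by 0.03 (± 0.11 SE). Mean levels in CD were low for Il23a (3.87), Il6 (3.95) and Trib3 (4.04), below the array medians of 4.88 to 4.94 over all probe sets. At such levels a small difference does not show that a gene was unchanged. Il6 and Il1b differed by 0.37 and 0.39 with SEs of 0.26 and 0.25, and Atf4, Ddit3, Trib3, Ccr7, Cd36 and Tlr7 differed by 0.17, 0.08, 0.03, -0.13, 0.24 and -0.34 without passing. The list as a whole was higher by a median of 0.20 (exact permutation p of list means = 0.0571, two-sided; adjusted p = 0.118 with an estimated correlation).

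Interferon-stimulated genes had the lowest median of the 43 lists. Of 32 measured members 29 were lower, with a median of -0.41 (1.33-fold lower), and adjusted over the list alone 21 fell and 1, Isg20, rose by 0.42. Dhx58, the RNA sensor LGP2, differed by -0.56 ± 0.10 (SE), Ifit2 by -0.84 ± 0.18, Rtp4 by -0.79 ± 0.18, Cmpk2 by -0.40 ± 0.10, Rsad2, viperin, by -0.87 and Mx1 by -0.69, and all 6 were among those that fell. The list's mean went from 7.68 ± 0.13 in CD to 7.28 ± 0.25 in HFD (SD, n = 4 each; exact permutation p = 0.0571, two-sided), so it did not pass that test, and its adjusted p was 0.344 with an estimated correlation.

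Genes of MHC class II presentation were lower, 12 of 15 below 0 with a median of -0.34 (1.26-fold lower). Adjusted over the list alone, 6 fell: H2-DMb1 (-0.57), H2-Aa (-0.48), H2-Eb1 (-0.45), H2-DMa (-0.42), H2-Ab1 (-0.38) and the transactivator gene Ciita (-0.36), and the protease gene Lgmn rose by 0.32. The list had an exact permutation p = 0.0857 (two-sided) and an adjusted p = 0.460 with an estimated correlation. Markers of the cDC1 subset, which cross-presents antigen, were lower by a median of -0.20, with 14 of 19 below 0. Of these Cd24a rose (0.58) when adjusted over the list alone and none fell. Cd8a differed by -0.42, Ifi205 by -0.65 and Tlr11 by -0.30 without passing. The list had an exact permutation p = 0.286 (two-sided) and an adjusted p = 0.503 with an estimated correlation. Its means on HFD replicates 1 and 4, 7.22 and 7.23, lay within the CD range of 7.18 to 7.27. The cDC1 call was lost without CD replicate 3, CD replicate 4, HFD replicate 2 or HFD replicate 3 (limma camera adjusted p from 0.0643 to 0.196). The cDC2 list missed the camera threshold (median -0.09, 15 of 19 below 0, limma camera adjusted p = 0.0552, adjusted p = 0.325 with an estimated correlation). It passed 2 other tests that none of the 6 called lower lists passed, the exact permutation test of list means (p = 0.0286, two-sided) and limma's fry (adjusted p = 0.0358), but with the replicate number as a block no list passed fry, and cDC2 had an adjusted p = 0.219. Adjusted over the list alone, Irf4 rose (0.80) and Cx3cr1 fell by 0.36. In the same arrays the plasma cell markers were higher by 0.91.

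**Figure D3:**
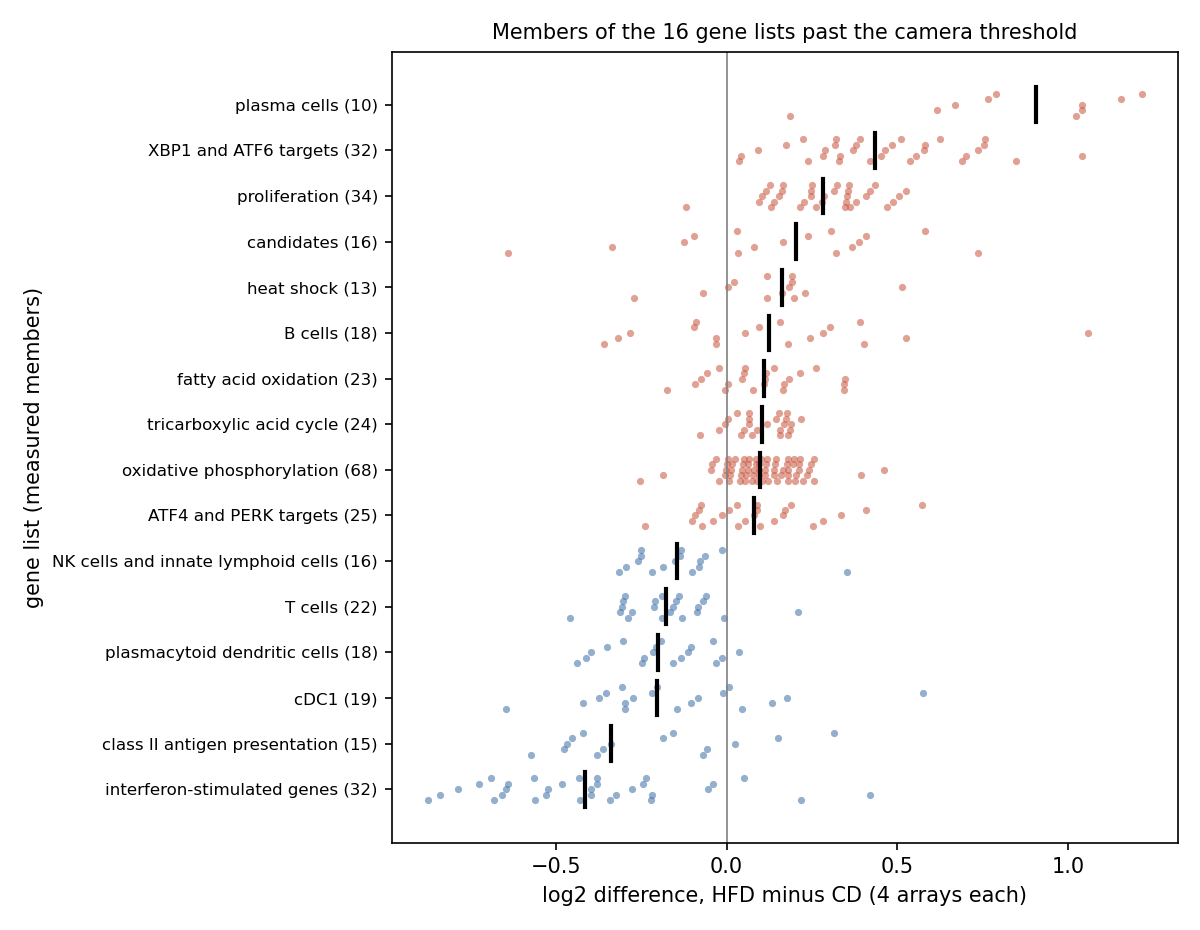
log2 difference, HFD minus CD (horizontal axis), of each measured member of the 16 called lists (vertical axis, with the number of members), with points for genes and black bars for list medians. The plasma cell list has the highest median, 0.91, and the interferon-stimulated genes have the lowest, -0.41.

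The T cell, NK and plasmacytoid lists were lower, while the B cell, macrophage and neutrophil lists had medians above 0. The macrophage and neutrophil lists were not called, and their exact permutation p of list means was 0.714 and 0.571 (two-sided). The neutrophil mean was highest on CD replicate 2, at 8.47, against 6.88 to 7.41 on the other CD arrays and at most 8.05 in HFD. The sort excluded cells by CD3, CD19, CD64 and Ly6G, and none of these marks NK or plasmacytoid cells. T cell markers had 21 of 22 members below 0 and a median of -0.18, with Cd6 at -0.46, Zap70 at -0.30, Ms4a4b at -0.28 and Cd3d at -0.31 (adjusted p = 0.355 with an estimated correlation). NK and innate lymphoid markers had 15 of 16 below 0 and a median of -0.14, with Il2rb at -0.31, Ncr1 at -0.29, Prf1 at -0.26 and Klrk1 at -0.25 (adjusted p = 0.460 with an estimated correlation). The mean level of this list, 9.66 in CD and 9.53 in HFD, lay above those of cDC1 (7.22 and 7.07) and cDC2 (7.42 and 7.34). Levels of different probe sets do not give shares of cells, so the purity of the sort was not measured. Plasmacytoid dendritic cell markers had 17 of 18 below 0 and a median of -0.20, with Smim5 at -0.44, Ccr9 at -0.41, Mpeg1 at -0.30 and Atp1b1 at -0.19 (adjusted p = 0.460 with an estimated correlation). No member of these 3 lists passed when adjusted over its list alone. The call of the NK list was lost without HFD replicate 1, where its median was -0.08 (limma camera adjusted p = 0.0764), and that of the plasmacytoid list without CD replicate 3, where its median was -0.10 (limma camera adjusted p = 0.0817).

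The other 26 lists were not called. Inflammatory cytokines had a median of 0.08 (limma camera adjusted p = 0.0665), with Il10 (0.70) the member that rose when adjusted over the list alone. Chemokines had a median of -0.05, with Ccl2 up by 0.60 and Cxcl9 at -0.52, both passing when adjusted over the list alone. Medians of signalling and stress lists were 0.00 for NF-kB targets, 0.04 for Toll-like receptor signalling, -0.03 for the inflammasome, 0.02 for hypoxia, 0.03 for antioxidant genes, 0.01 for apoptosis, where Trp53inp1 rose (0.62, adjusted over the list alone), and 0.00 for autophagy and lysosome. Medians of metabolic lists were 0.01 for glycolysis, 0.04 for lipid uptake and storage, 0.06 for cholesterol synthesis (limma camera adjusted p = 0.0598) and -0.02 for fatty acid synthesis. Class I antigen presentation had a median of -0.10, with Calr (0.42) and Pdia3 (0.29) rising and Tap1 (-0.25) falling when adjusted over the list alone, and dendritic cell maturation had a median of -0.06. Immediate early genes had a median of 0.01, with Fos (0.71) and Jun (0.45) rising when adjusted over the list alone, and ribosomal proteins had a median of 0.01. Among cell type lists, medians were -0.01 for Langerhans and dermal dendritic cells, where Epcam (0.82) and Cd24a rose, 0.03 for macrophages and monocytes, where Slpi (1.07) rose, 0.21 for neutrophils, -0.08 for fibroblastic stroma, where Fn1 (1.01) rose, -0.02 for endothelium, where Vwf (-0.36) fell, -0.01 for keratinocytes, -0.01 for adipocytes, 0.04 for mast cells and basophils and -0.02 for red cells and platelets, each named gene adjusted over its list alone. The median, the mean and the camera direction differed in sign for the NF-kB, Toll-like receptor, Langerhans, keratinocyte, adipocyte and autophagy lists.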

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

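The tests of the segment median, of the XBP1 and ATF6 list mean after corrections of array signal and of the T cell list against the plasma cell list were chosen only after related results had been seen. The T cell test took the place of an earlier one on the T and NK lists alone, which did not decide (exact permutation p = 0.0857 and 0.114). For the plasmacytoid markers, an r of 0 or below was to exclude the explanation; that it must also lie beyond its spread was required only after r had been seen.

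Of the 35 splits of the 8 arrays into 4 and 4, only the real one, 1 split, called as many as 7 genes. The highest of the others called 1. That is the smallest share that 35 splits allow, so it argues against chance for the gene count but cannot exclude it. For the lists, 2 of the 35 splits called as many as the real 16, the highest other calling 18, so chance cannot be excluded for the list count.

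Single arrays stood apart from the other 3 of their diet in 8 of the 258 groups of 4 arrays tested (86 genes and 43 list means in each diet), where chance alone gives about 12.9. The gap to the nearest array, as a share of the whole range, was 0.886 for Il1b on HFD replicate 3, at 10.01 against 9.29 to 9.37. It was 0.913 for Sec24d on CD replicate 3, at 7.13 against 6.76 to 6.79. For Cd6 it was 0.899 on HFD replicate 1, at 5.86 against 5.65 to 5.67, and for Klrk1 it was 0.945 on the same array, at 9.81 against 10.06 to 10.08. The mean of the fatty acid synthesis list was low on CD replicate 2 (share 0.892), as was that of class I antigen presentation (0.862). The fibroblastic stroma list was low on HFD replicate 3 (0.832) and the keratinocyte list on CD replicate 3 (0.834).

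XBP1 and ATF6 targets were higher in HFD together with plasma cell genes. A shift of array medians was argued against as the whole cause, since these differed by only -0.024 (HFD minus CD). The list's mean differed by 0.41 ± 0.07 (SE) after quantile normalization and by 0.48 ± 0.08 after centring on array medians (exact permutation p = 0.0286 each), against 0.45 ± 0.07 before. These corrections moved a gene's difference by at most 0.108 and 0.024, so they could not have removed the rise. The list's median lay at percentile 100 of 10000 random lists matched on level. So did that of the neutrophil list (exact permutation p of its means = 0.571), so the percentile does not decide. Other technical components were not tested. A candidate explanation that stays open is a larger share of plasma cells or plasmablasts among the sorted cells. Immunoglobulin segments had a median of 0.63 (exact permutation p of their means = 0.0286). The set was drawn up after the values were seen and holds the 3 segments that passed over all genes. Its direction was thus partly known beforehand. Within diets the mean of the segments followed that of 31 targets with r = 0.955 over the 8 arrays. The gate removed CD19-positive cells and required CD11c and MHC class II, which mature plasma cells largely lack. By contrast, transcripts that plasma cells hold in abundance read 13.0 in CD and 13.2 in HFD for Ighm. Levels were 12.9 and 13.3 for Igkv5-43 and 10.7 and 11.4 for Jchain. Of the 10 plasma list genes 1, Derl3, is also in the XBP1 and ATF6 list. That counts shared symbols only and does not show that the plasma cell list is independent of the ER genes. Of 11 plasma cell identity genes outside the ER and the fixed lists, 7 were higher and 4 lower. Their median was only 0.05 (exact permutation p of their means = 0.0286). A response of dendritic cells to the diet beyond the immunoglobulin signal stays open: with the segment mean as a covariate the diet difference of the targets was 0.0829 ± 0.0541 (SE, 95% interval -0.06 to 0.22), against 0.44 without it (0.26 to 0.61), an interval that holds 0 and changes of some size alike, and since that covariate is itself a measured outcome, the fit cannot separate secretory activity in dendritic cells from RNA of other cells.

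The class II and cDC1 lists had medians below 0 in HFD, but neither passed the exact permutation test of list means (p = 0.0857 and 0.286, two-sided). A lower share of dendritic cells with every other cell type in their place could not be decided. T cell markers had a median below 0, but their list did not pass alone (exact permutation p = 0.0857). The gap between the T cell and plasma cell lists was -1.03 (exact permutation p = 0.0286). Since the plasma cell list passed alone, the gap shows only that these lists did not move alike, not that T cell markers fell. A lower share with plasma cells alone in their place could not be decided: pan-dendritic genes had a median of -0.0752 (exact permutation p of their means = 0.314), with 14 lower and 5 higher. Adjusted over the list alone, Zbtb46 (-0.36) and Dpp4 (-0.43) fell, while Itgax at -0.28 did not pass. The diet stays open as an untested biological explanation.

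Interferon-stimulated genes were lower in HFD. Fewer plasmacytoid dendritic cells among the sorted cells could not be decided: within diets r between the markers and the interferon-stimulated genes was -0.19 (exact permutation p = 0.714, one-sided), but 0.27 without CD replicates 2 and 3, so the sign lay within its spread. A general dilution of dendritic transcripts was not decided either, as the interferon-stimulated median lay below the pan-dendritic median by a difference of -0.34, while the corresponding difference of list means, -0.30, had an exact permutation p = 0.0571. The diet stays open as an untested biological explanation.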

How the results depend on the processing

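Testing all probe sets and dropping plasma list genes were chosen after seeing the data. Against 6 genes higher and 1 lower, an intensity trend with a robust prior gave 107 and 11, and genes at or above the median level gave 82 and 12, each holding all 7 genes. A threshold of 0.1 gave 45 and 6, and the first residual component as a covariate gave 10 higher. All probe sets tested on their own gave 0 and 0 (lowest limma adjusted p 0.119, 3518 at an unadjusted p under 0.05). There more tests enter the adjustment and the variance prior is fitted over all 41345 probe sets. These 2 changes were not told apart. Leaving out each array gave 0 to 22 genes higher and 0 to 15 lower, both highest without HFD replicate 1, and 0 of each without CD replicate 2, CD replicate 4 or HFD replicates 2, 3 or 4. The cause of these shifts was not tested, beyond fewer arrays or genes entering the fit. The replicate block gave 3 genes higher and 1 lower, with 1 of the 7 genes kept, and 10 and 6 lists. Same-number arrays of the diets deviated together with r of 0.09, 0.02, 0.05 and 0.05, small values. Arrays of unlike numbers had r from -0.064 to 0.026, below all of these but that of replicate 2. In each diet 3 of 4 arrays correlated best with their own number, so a tie between equal numbers cannot be dismissed. For the lists, an estimated correlation gave 0 higher and 0 lower and fry gave 5 and 1, the lower list by fry being cDC2 and none of the 6 called lower lists passing it, and with the replicate block fry gave none (lowest adjusted p 0.0872), while 16 other settings for each direction stayed within 1.5 times. With arrays left out, separation ran from 0.00382 without HFD replicate 3 to 0.0107 without CD replicate 2, and it was 0.00111 over all genes and 0.0193 over genes at or above the median level. With arrays left out, Il12b ran from -0.0281 (without CD replicate 1) to 0.135, Trib3 from -0.0260 (without CD replicate 3) to 0.117 and Ccr7 from -0.252 to 0.0429 (without HFD replicate 2), with signs turned, the cause not tested. Of the single genes' other values, 1273 kept their direction and side of the threshold, 43 newly passed and 50 no longer passed. For list values these were 251, 0 and 38. The XBP1 and ATF6 median was 0.42 without plasma list genes. Dim probe sets, near the background, limit what small changes can be seen.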

Other observations

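The sets and the test in this part were chosen only after the data were seen. Sets of secretory and other genes drawn up by symbol partly overlap the fixed lists. Of 31 genes of the translocon, the oligosaccharyltransferase and the signal peptidase 30 were higher, by a median of 0.33, and 24 rose when adjusted over the set alone (exact permutation p of the set means = 0.0286; adjusted p = 0.0353 with an estimated correlation over 6 such sets). Without 5 of them that a fixed list holds, 25 of 26 were higher, by a median of 0.31. Golgi and vesicle coat genes were higher for 36 of 44, by 0.18, with 9 rising when adjusted over the set alone (exact permutation p of the set means = 0.0286; adjusted p = 0.0353 with an estimated correlation). Without Sec24d, a fixed-list gene, and Tmed6, which had passed over all genes, 34 of 42 were higher, by 0.16. Core histone genes were above 0 for 23 of 33, with a median of 0.05, and did not pass (exact permutation p of the set means = 0.114; adjusted p = 0.124 with an estimated correlation). Proteasome subunits were higher for 34 of 38, by 0.12, and mitochondrial ribosomal proteins for 59 of 71, by 0.11, with exact permutation p of the set means of 0.0286 and 0.0571 and adjusted p of 0.0752 and 0.128 with an estimated correlation. Without 3 proteasome genes of fixed lists 34 of 35 were higher (exact permutation p of the means = 0.0286). All 3 were among the 4 lower genes of the set, so their removal does not check the rise. The immunoglobulin segments, with the 3 that passed over all genes kept in, had an adjusted p of 0.0183 with an estimated correlation. Among them Ighv1-54 had the largest difference, 1.51 ± 0.30 (SE), and Igkv9-124 the smallest, 0.23 ± 0.41.

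Plasma cell identity genes outside the ER, a list of 20 with 19 measured and 15 higher, had a median of 0.21 (exact permutation p of the list means = 0.0286). Adjusted over it alone 8 rose, among them Irf4 (0.80), Sdc1, the syndecan CD138 (0.79), and Jchain (0.67). Of the 19, 8 are also in fixed lists: Tnfrsf17, Sdc1, Prdm1 and Jchain in the plasma cell list, Pou2af1 and Ighm in the B cell list, Irf4 in cDC2 and Cd28 in the T cell list. Without them 7 of 11 were higher, by a median of only 0.05 with 2 rising when adjusted over the rest alone (exact permutation p of the means = 0.0286). Plasmacytoid markers outside the interferon list were lower for 14 of 15, with a median of -0.21 (exact permutation p of the list means = 0.143).

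Proliferation genes were higher in HFD, and dividing plasmablasts among the sorted cells were a candidate source. Within the diets the mean of the proliferation list showed no positive relation to that of the immunoglobulin segments: r was -0.11 and rho -0.14 over the 8 arrays (exact permutation p = 0.594 and 0.635, one-sided, 0.714 and 0.724 adjusted over 3 relations), and r was -0.50 without CD replicate 3 and HFD replicate 3. The test leaves that source undecided, and whether this relation differs from that of the XBP1 and ATF6 targets was not tested.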
